A study of Mus musculus with 2 samples.

How the data were processed

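Chromatin immunoprecipitation with an antibody against H3K9me3 was followed by sequencing in neural tube tissue of B6NCrl mouse embryos at day 12.5. The labels give 1 group with 2 biological replicates, each a pool of tissue from both sexes, from 120 embryos for replicate 1 and 88 embryos for replicate 2. A control experiment is listed in the labels as a possible control for both libraries, and its data were not used here. Per the labels' assembly entry and the deposited readme files, coordinates are on mm10. The aligner, the peak caller and its settings are not given in the sources used here.

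The authors deposited 4 peak lists in narrowPeak format, 1 per replicate, 1 for both replicates together and 1 of replicated peaks. Per the deposited readme files, the list of replicate 1 was derived from its alignments and 2 further files of unstated kind, and the list of replicate 2 from its alignments and 1 further file. The rule that made a peak replicated is not given in the sources used here; all 31092 rows of the replicated list were also rows of the list of both replicates together. Each row carries the authors' fold enrichment, a linear ratio, and the −log10 of the p and q values that the authors' peak caller gave, per the deposited format. These are values of single peaks from single lists. They were used here only to describe, rank or filter peaks within a list, apart from the correlation between the replicates' lists. The files hold no read totals, so the depth of each library is unknown and no counting interval was computed. A locus without a peak may lie below the authors' threshold.

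The lists were read as deposited, without further filtering. Of the peaks of all 4 lists, 0 reached beyond the chromosome ends of GRCm38, the assembly that mm10 names. Genes and transcripts came from GENCODE release M21 and sequence with repeat masking from the GRCm38 reference. Coordinates are printed counting from 1. Peaks on unplaced contigs (261 in the replicated list) were left out of tests, since the annotation used covers the main chromosomes. A peak and a feature were taken as overlapping when they shared at least 1 base. A promoter was the stretch within 1 kb of any annotated start of a protein-coding gene. Peak midpoints were assigned in the order promoter, other exon, intron, intergenic. Exons and introns were those of all annotated gene types, including pseudogenes and non-coding genes.

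The main test was a circular-shift permutation test, two-sided, in which all peaks of a chromosome were moved by 1 random offset within the sequenced span, with 1000 shifts and seed 20260. It keeps peak widths, peak spacing and peak number per chromosome, and gene length and gene clustering. The smallest p it can give is 0.0020. The 17 gene lists, the tests and the alternatives were fixed before the data were examined. For each list the genes with a replicated peak in the body and the genes with one near a start were counted, and the 34 tests were adjusted together by the Benjamini-Hochberg method, with 0.05 as the threshold. All members were protein-coding genes, except that the imprinted list took any gene type. Villin and Tasor matched no symbol in the annotation, whose names for these genes (Vil1 and Fam208a) were also in the lists. Rpl10l is a member of both the ribosomal and the germline list. For zinc finger genes over 4 kb, an exact two-sided sign test compared genes with a peak only in the last 2 kb with genes with a peak only in the first 2 kb. Between replicates, Spearman's rho and Pearson's r of log2 fold were taken over overlapping peaks, with 10000 permuted pairings. Peaks are not independent replicates, so these p-values describe these 2 libraries, and all shift tests take the peaks of these 2 pools as given.

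Named genes followed a rule fixed in advance: the 10 protein-coding genes with the most bases in replicated peaks, the 10 with the strongest replicated peak by fold within 1 kb of a start, and up to 3 members per list by the strongest peak in the body. The 10 strongest peaks and the 10 windows of 1 Mb with the most covered bases were added. A gene was called reproduced when each replicate's own list also overlapped it. The replicated list came from the same 2 libraries, so this is not an independent check.

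Alternatives fixed before the data were examined were a −log10 p of at least 5, the strongest 50% of peaks by fold, each replicate's own list, the list of both replicates together, reciprocal overlap of 50% (100 shifts), the reverse direction of overlap, −log10 p in place of fold, Fisher's exact test against other protein-coding genes, at least 10% of the gene body covered, a 2 kb promoter window, 1 kb end windows, shares of covered bases and windows of 500 kb. Alternatives chosen after seeing the data kept only peaks that overlapped both replicates' own lists, peaks with under 80% repeat-masked bases, peaks with at least 90% of their 32-base words unique in the main chromosomes, or peaks at or below the GC content of shifted positions. A further one took the replicate 2 peaks with a −log10 p of at least 5. The alternative with 10% of the gene body was first run with 200 shifts, with which 0 lists passed and the smallest adjusted p was 0.0564. It was rerun with 1000 after that was seen. The scan of gene families in the closing section was likewise first run with 1000 shifts, with which 0 families or gene types passed and the smallest adjusted p was 0.0530. It was rerun with 5000 shifts and new offsets after that was seen. For alternatives, a direction was read only where the main or the alternative value passed its threshold. The shares on chromosome 7 and in the densest windows, which had no test, were compared with the SD between the replicates' own lists. Counts of peaks, of lists that passed and of named genes were taken as little changed within a ratio of 1.5.

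The scripts were tested on simulated data. With peaks moved to random offsets, 2.06% of 680 list tests over 21944 genes had a p under 0.05, and 0 passed the adjusted threshold. Peaks planted at the starts of 15 genes in random lists of 30 were found at an unadjusted p under 0.05, with 200 shifts per draw. This held in 20 of 20 draws for gene bodies and in 20 of 20 for promoters. These lists were random genes and not clustered families, and the adjusted threshold was not applied to them. For the end test, 60 planted last ends and 20 planted first ends among 80 genes were all recovered. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 were used.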

Results

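H3K9me3, a histone mark of heterochromatin, was mapped by ChIP-seq in the neural tube, the precursor of the brain and spinal cord, of mouse embryos at day 12.5. The study has 1 group of 2 biological replicates, pools of tissue from 120 embryos (replicate 1) and 88 embryos (replicate 2). With no other group, the comparisons are between the replicates, between peaks and their chance placement in the genome, and between classes of genes. The peak list of replicate 1 held 63921 peaks covering 19.3 Mb, and that of replicate 2 held 66289 peaks covering 21.5 Mb. Both lists include weak calls: the lowest −log10 p was 2.01 in replicate 1 and 2.02 in replicate 2, with medians of 4.42 and 4.70. Calling on both replicates together gave 86346 peaks. Read totals are not part of the files, so the depth behind each list is unknown. Fold enrichments below are the authors' own values for single peaks.

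The replicated list, on which the gene comparisons rest, held 31092 peaks covering 17.0 Mb. Their median width was 442 bp (range 185 to 12446 bp) and their median fold enrichment 2.92 (interquartile range 2.60 to 3.24, highest 9.37). Of these peaks, 23887 (76.8%) overlapped peaks in both replicates' own lists, 2993 (9.63%) overlapped replicate 1 alone and 3981 (12.8%) replicate 2 alone. The remaining 231 (0.743%) overlapped neither list.

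Peaks of replicate 1 overlapped those of replicate 2 far more often than chance gave, and strong peaks did so more often than the list as a whole. Over the main chromosomes, 26009 of 63566 replicate 1 peaks (40.9%) overlapped a replicate 2 peak, against 1.81% ± 0.28 (SD over shifts) by chance (permutation p = 0.0020, the smallest that 1000 shifts can give). The share was 64.3% among the 18267 replicate 1 peaks with a −log10 p of at least 5, and it was 23.1% when 50% of both peaks had to overlap. In the other direction, 38.9% of 65957 replicate 2 peaks overlapped replicate 1. Across the 26009 overlapping peaks, log2 fold enrichment in the replicates gave a Spearman's rho of 0.26 and a Pearson's r of 0.31 (permutation p = 0.0001 for both, the smallest that 10000 pairings can give). This correlation is across peaks, which are not independent replicates.

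Replicated peaks lay between genes and in exons more often than chance gave, and less often in introns and at promoters. By midpoint, 59.2% were intergenic against 50.8% ± 1.5 (SD) in shifted positions, and 5.86% lay in exons against 4.15% ± 0.22. Exons of all gene types were counted, pseudogenes included, so the exon excess does not show an excess in coding exons. Introns held 31.8% against 40.9% ± 1.4, and the stretches within 1 kb of protein-coding starts held 3.10% against 4.16% ± 0.32. The permutation p was 0.0020 for each of the 4 classes. The promoter deficit did not pass when covered bases were counted in place of midpoints (3.77% against 4.19%, permutation p = 0.246). Of the 21938 protein-coding genes, 849 had a replicated peak within 1 kb of a start, 0.765 times the number in shifted positions (permutation p = 0.0020), and 3904 had one in the body, 0.949 times (permutation p = 0.0280). This small body deficit did not pass with a −log10 p of at least 5 (permutation p = 0.120), with the strongest 50% of peaks (0.583) or in replicate 1's own list (0.0919). Nor did it pass in 3 settings chosen after seeing the data: peaks found in both own lists (permutation p = 0.210), peaks with under 80% masked bases (0.0859) and peaks of unique words (0.617). It did pass in replicate 2's own list (0.903 times, permutation p = 0.0020) and for both replicates together (0.912 times, p = 0.0020). With peaks at or below the GC content of shifted positions, also chosen after seeing the data, it passed too (0.904 times, permutation p = 0.0140). It turned into an excess of 1.33 times when 10% of the body had to be covered (permutation p = 0.0080).

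Zinc finger genes, clustered protocadherins and vomeronasal receptors carried the mark more often than chance gave, while olfactory receptors, Hox, histone and X-linked reproductive genes, which also lie in clusters, did not pass. Zinc finger genes, which encode DNA-binding repressors in large part, had a replicated peak in 181 of 428 gene bodies, 2.35 times the 77.1 ± 13.4 (SD) of shifted positions. In 172 of these 181 genes each replicate's own list also had a peak, which is not an independent check, since the libraries are the same. The ratio was 1.71 both without replicate 1 and without replicate 2. The clustered protocadherins, which encode cell adhesion proteins that give neurons individual surface identities, had one in 53 of 57 bodies, 2.83 times the shifts. The vomeronasal receptors, which detect pheromones, had one in 108 of 327, 2.31 times the shifts. The adjusted permutation p was 0.0097, 0.0255 and 0.0097, respectively. With peaks at or below the GC content of shifted positions, chosen after seeing the data, the protocadherin bodies no longer passed (40 of 57, 6.32 times, adjusted permutation p = 0.0951). Olfactory receptors had 105 of 1093 bodies (1.43 times, adjusted permutation p = 0.622).

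Imprinted and germline genes carried peaks both in the body and at the start. Of 31 genes at imprint control regions, 28 had a replicated peak in the body (3.24 times the shifts) and 25 within 1 kb of a start (11.7 times). A peak counts for every listed gene that it overlaps, so these are counts of genes and not of separate peaks. Among the genes with a peak at a start were Peg3, Snrpn, Kcnq1ot1, Airn, Grb10, Plagl1 and Meg3. H19 and Dlk1, chosen after their values were seen, had no replicated peak in the body or within 1 kb of a start. The positions of the control regions themselves were not used here, so this does not show whether those carried a peak. The strongest body peaks of this list lay in Mest (chromosome 6, 30736379 to 30739016, fold 4.69), Blcap (chromosome 2, 157558405 to 157559895, fold 4.59) and Gnas (chromosome 2, 174296069 to 174301187, fold 4.55). Of 30 genes used in germ cells, 17 had a body peak (2.69 times) and 13 a peak at a start (9.63 times), among them Dazl, Sycp1, Sycp2, Sycp3, Stk31 and Taf7l. The strongest body peak of the list lay in Ddx4, an RNA helicase gene of germ cells, and reached over its start (chromosome 13, 112651676 to 112652609, fold 5.08). It was followed by peaks in Mael (fold 4.46) and, inside the gene, in Tdrd9 (fold 4.10), which act in the piRNA pathway that silences transposons. All 4 of these tests gave an adjusted p of 0.0097. In the replicates' own, longer lists all 4 still passed, with lower ratios: 2.09 and 1.99 times without replicates 1 and 2 for imprinted bodies, 6.74 and 6.31 at imprinted starts, 5.99 and 5.45 at germline starts, and 1.73 without replicate 2 for germline bodies. With the same low-GC peaks, 18.5% of the placed peaks, imprinted and germline genes had 0 peaks at starts. Shifts gave 0.482 ± 0.736 and 0.264 ± 0.516 there, so 0 shows no deficit. For bodies neither list passed with these peaks (2.42 and 0.695 times, adjusted permutation p = 0.348 and 1). When at least 10% of the gene body had to be covered, 1 germline gene remained and the list no longer passed (2.69 times, adjusted permutation p = 1).

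At starts, the protocadherins stood highest: 51 of 57 genes had a replicated peak within 1 kb of a start, 33.5 times the 1.52 ± 3.69 of shifted positions (adjusted permutation p = 0.0097). All 51 also had one in each replicate's own list, which comes from the same libraries and is not an independent check. The ratio was 17.9 without replicate 1 and 18.6 without replicate 2. Zinc finger genes (46 of 428, 1.85 times, adjusted permutation p = 0.163) and vomeronasal receptors (43 of 327, 2.24 times, adjusted p = 0.128) did not pass at starts. Vomeronasal receptors did pass with 2 kb around a start (67 of 327, 2.44 times, adjusted permutation p = 0.0170) and without replicate 1 (2.22 times, adjusted p = 0.0255). They also passed with low-GC peaks (5.83 times, adjusted permutation p = 0.0226) and with peaks of unique words (2.57 times, adjusted p = 0.0453), both chosen after seeing the data.

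**Figure D1:**
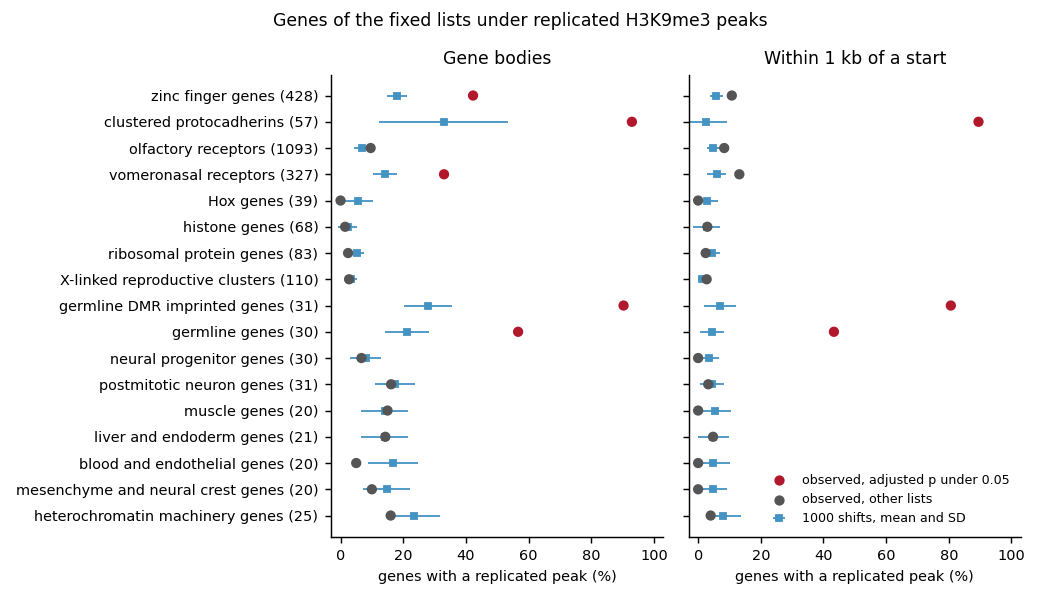
Percent of the genes of each fixed list (number of genes in brackets) with a replicated peak in the gene body (left) or within 1 kb of a start (right), with the mean and SD of 1000 shifts as blue squares and bars. Protocadherins and imprinted genes lie farthest from the shifts in both panels, and the neural, muscle, liver and blood lists lie close to them.

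The genes that pattern the neural tube had few or no replicated peaks, and few were due by chance. The 39 Hox genes had 0 peaks in the body and 0 at starts (2.13 ± 1.92 and 1.16 ± 1.35 in shifts, adjusted permutation p = 0.904 and 1), but 4 of 39 had a body peak without replicate 2 (0.893 times). With Fisher's exact test against other protein-coding genes, which ignores gene length and clustering, the Hox bodies passed as a deficit (6.95 expected, adjusted p = 0.0018). Of 30 neural progenitor genes, 0 had a peak at a start and 2 had one in the body, against 2.40 ± 1.45 in shifts (adjusted permutation p = 1). These were Pax7 (strongest peak on chromosome 4, 139748592 to 139749075, fold 3.25) and Pax3 (chromosome 1, 78116852 to 78117249, fold 2.28), regulators of dorsal progenitors. Of 31 genes of postmitotic neurons, 5 had a body peak, and Chat, for the enzyme that makes acetylcholine, was the single one with a peak at a start. Without replicate 2, 16 of 31 had a body peak (1.60 times, adjusted permutation p = 0.0883), and without replicate 1, 4 of 31 had one (0.413 times, adjusted p = 0.0679). Neither passed, and the difference between them was not tested. The neurofilament gene Nefm had the strongest of these peaks (fold 3.86).

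Genes of other lineages differed as little from the shifts. Body peaks were found in 3 of 20 muscle genes (Ckm, Ryr1 and Myh8), 3 of 21 liver and endoderm genes (Cyp3a11, Hnf1a and Serpina1b), 1 of 20 blood and endothelial genes (Tek) and 2 of 20 genes of mesenchyme and neural crest (Col1a1 and Erbb3). The adjusted p lay between 0.622 and 1 for these 4 lists. Cyp3a11, a liver cytochrome P450 in a cluster of related genes, was 33.8% covered, by 15 peaks. Among 25 genes for writers, readers and cofactors of H3K9 methylation, 4 had a body peak against 5.82 ± 2.10 in shifts (adjusted permutation p = 1). The strongest lay in Smchd1 (fold 5.27), a regulator of X inactivation, and Atf7ip and Hells had weaker ones (fold 3.71 and 3.32). Replication-dependent histone genes had 1 of 68, Hist1h2aa. Ribosomal protein genes had 2 of 83, Rpl10l and Rpl39l, of which neither had a body peak in both replicates' own lists. Multicopy reproductive genes of mostly X-linked families had 3 of 110 (Pramel5, Rhox13 and Ssxb5). None of these 3 lists passed (adjusted p from 0.879 to 1), but ribosomal protein genes passed as a deficit without replicate 1 (1 of 83 against 7.56 ± 2.53, 0.132 times, adjusted permutation p = 0.0302). With Fisher's exact test all 3 lists passed as deficits for bodies (0.0824, 0.135 and 0.153 times for histone, ribosomal and reproductive genes).

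Within zinc finger genes the mark lay toward the 3′ end, where the exons for the zinc fingers are. Of 415 zinc finger genes over 4 kb, 87 had a replicated peak in the last 2 kb alone, 7 in the first 2 kb alone and 13 in both. The last end thus made up 92.6% of the genes with a peak at a single end (exact two-sided sign test, p = 1.1e-18). In the other 18279 protein-coding genes this share was 55.8%, with 314 against 249 genes (exact sign test, p = 0.0069). For these other genes it was 50.4% in the peaks of replicate 1 alone (exact sign test, p = 0.779) and 51.4% with windows of 1 kb (p = 0.575). The sign tests take genes as independent and, unlike the shifts, do not keep the clustering of genes and peaks. Zfp810 (chromosome 9, 22276703 to 22277918, fold 7.32), Zfp945 (chromosome 17, 22853062 to 22854076, fold 6.74) and Zfp2 (chromosome 11, 50899784 to 50902938, fold 6.35) had the strongest body peaks of the list. Zfp2 was 72.4% covered, by 12 peaks.

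**Figure D2:**
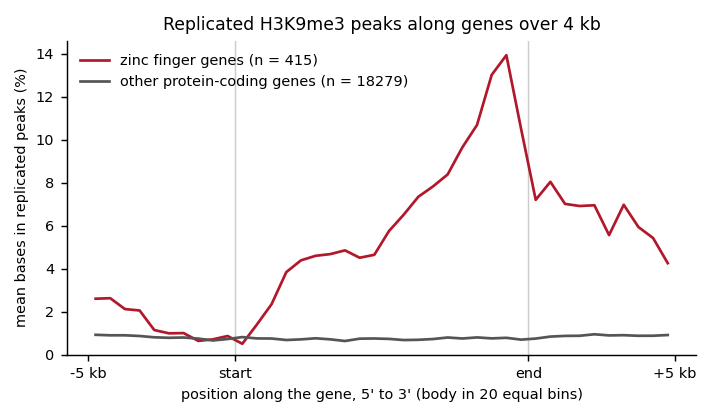
Mean percent of bases in replicated peaks along 415 zinc finger genes and 18279 other protein-coding genes over 4 kb, in 20 equal bins of the gene body and 5 kb on either side. Zinc finger genes reach 13.9% near the 3′ end, while the other genes stay under 1% throughout.

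The protocadherin clusters on chromosome 18 formed the densest stretch of the mark. In the window from 37000001 to 38000000, 280 replicated peaks covered 250.6 kb, with 207.1 kb in replicate 1 and 235.0 kb in replicate 2, the first rank in both. Replicated peaks covered 50.1% of the gamma cluster, 37.1% of the beta cluster and 19.2% of the alpha cluster. All 22 beta genes had a body peak, as did 13 of 14 alpha and 18 of 21 gamma genes. The 10 protein-coding genes with the most covered bases were all models of this locus, 7 gamma genes led by Pcdhga1 (64 peaks, 90.1 kb, 50.1% of its body) and 3 long read-through models. These models overlap, so the same peaks count for many of them. No replicated peak lay at the 3′ end that the gamma models share, where 10-kb bins from 37800001 to 37850000 were 0% covered. The strongest peak of the gamma cluster lay at 37752121 to 37754782 (fold 6.64).

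**Figure D3:**
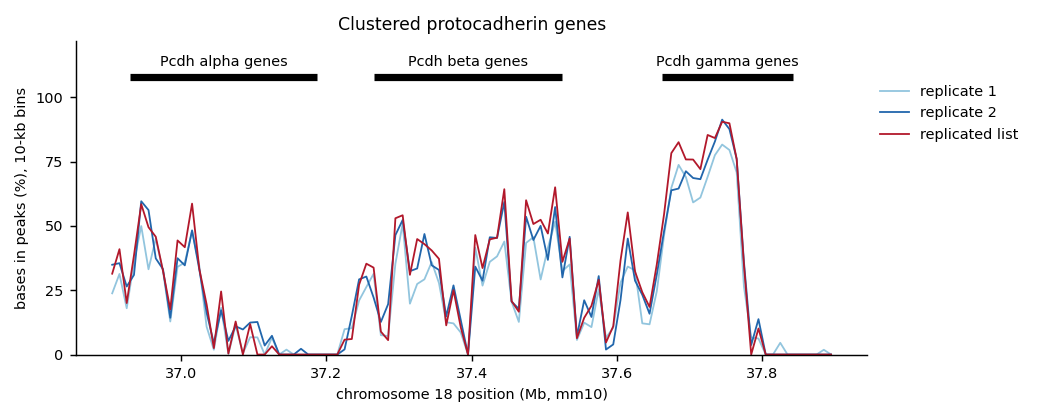
Percent of bases in peaks in 10-kb bins along the protocadherin clusters of chromosome 18 (mm10), for each replicate's own list and the replicated list, with the extent of each cluster as a bar. Both replicates follow the same course, with the highest coverage over the gamma cluster.

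Outside this locus, the strongest replicated peak of the genome, with a fold of 9.37, covered 90.8% of the intronless transcription factor gene Klf14 (ENSMUSG00000073209; peak on chromosome 6 from 30956275 to 30959050). Further strong peaks near an annotated start lay at Tcfl5, a transcription factor gene of the testis (chromosome 2, 180642678 to 180644670, fold 6.44), and at 6 gamma protocadherins. The zinc finger genes Zfp930 (chromosome 8, 69224926 to 69226598, fold 6.22) and Zfp810 (chromosome 9, 22281417 to 22283439, fold 6.05) also ranked here. Their peaks lay near starts inside the gene and not at its 5′ end, which is at 69209038 for Zfp930 and 22307648 for Zfp810. Klf14 and these 9 further genes, 10 in all, each had a peak within 1 kb of a start in both replicates' own lists. Of the 10 strongest peaks, 5 lay on main chromosomes without overlapping an annotated gene, and 1 lay on an unplaced contig, for which no genes were read.

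The mark was concentrated in few regions, above all on chromosome 7. The 5% of 1-Mb windows with the most covered bases held 48.9% of all bases in replicated peaks. Chromosome 7 had 4834 peaks, or 33.9 per Mb (57.0 in replicate 1 and 61.1 in replicate 2) and 15.7% of all placed peaks, followed by chromosome 17 with 23.3 per Mb. Of the 10 densest windows, 6 were on chromosome 7. The second densest, from 33000001 to 34000000, held 193.5 kb of peaks and 12 secretoglobin genes. Windows from 17000001 and from 18000001 held pregnancy-specific glycoprotein and Ceacam genes, with 182.4 kb and 134.8 kb of peaks. Windows from 12000001 (12 vomeronasal receptor and 9 zinc finger genes), 23000001 (18 vomeronasal receptor genes) and 10000001 (9 vomeronasal receptor genes) held 143.5, 133.7 and 132.9 kb. On chromosome 13, the window from 61000001 held 8 cathepsin genes and 169.7 kb of peaks. The window from 114000001 on chromosome 12 held no protein-coding gene but 49 immunoglobulin variable gene segments, with 178.8 kb of peaks, and the last, from 121000001 on chromosome 4, held 159.7 kb. All 10 windows ranked among the first 14 in each replicate.

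The X chromosome was sparse in the replicated list (530 peaks, 3.16 per Mb), and the replicates differed on it. It had 7.89 peaks per Mb in replicate 2's own list but 16.4 in that of replicate 1. The latter was close to chromosomes 1 (16.0) and 14 (16.2) in the same list, so replicate 1 alone did not show a sparse X. Replicate 1 had 2755 X peaks and replicate 2 had 1325, a ratio of 2.08, while the ratio lay between 0.907 and 1.01 on every autosome. The Y chromosome had 9 replicated peaks.

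**Figure D4:**
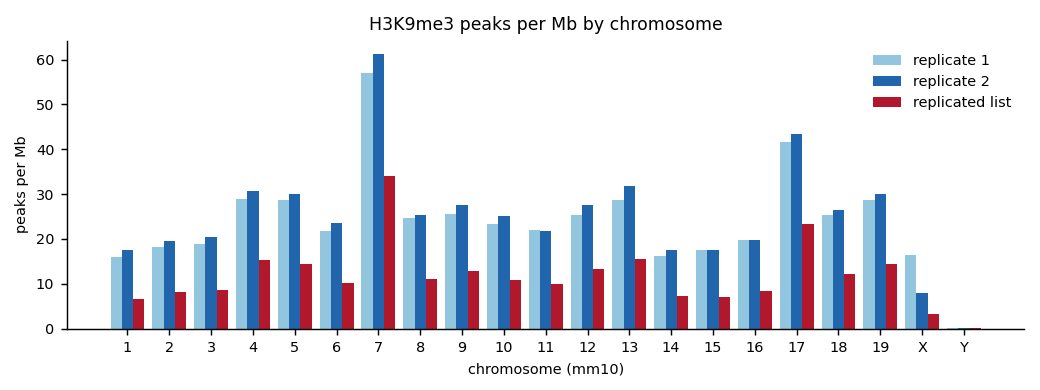
Peaks per Mb of sequenced span on each chromosome (mm10) for replicate 1, replicate 2 and the replicated list. Chromosome 7 stands highest in all 3 lists, and the X chromosome is the one where replicate 1 has far more peaks than replicate 2.

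Replicated peaks were richer in G and C than shifted positions on the same chromosomes, and no difference was found in their share of repeat-masked bases. Their GC content was 46.3%, against 42.1% ± 0.28 (SD) in shifted positions (permutation p = 0.0020). Repeat-masked bases made up 33.4% against 33.9% ± 0.76 (permutation p = 0.521). All classes of repeat were counted together, and how reads that match several places were handled is unknown. The value thus does not show whether repeats carried the mark. In the peaks of replicate 1 alone the masked share was lower than in shifts (32.3% against 34.1%, permutation p = 0.0020).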

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

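The replicated list held a signal outside the sequence used in the comparisons: 261 replicated peaks lay on unplaced contigs, 61 of them on Un_JH584304, where replicate 1 had 66 peaks and replicate 2 had 69. One of the 10 strongest peaks, with a fold of 7.90, covered bases 30544 to 36128 of the contig 4_GL456216_random. No biological explanation was tested for these peaks.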

How the results depend on the processing

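Among 114 alternative values of the main results, 93 kept their direction and their side of the threshold or moved little, and all tests of zinc finger 3′ bias, replicate overlap, replicate correlation, GC content and the exon, intron and intergenic shares did so under every alternative run. The causes of the other changes were not tested unless stated. By construction, the peak count moved to 15546 for the strongest 50% of peaks, to 86346 for both replicates together and to 63921 to 66289 for single replicates. By covered bases the promoter ratio was 0.901 and did not pass. With Fisher's exact test, which ignores clustering of genes and peaks and gene length, 10 lists in place of 5 passed for bodies and 6 in place of 3 for promoters, and all 5 gained for bodies were deficits: Hox, histone, ribosomal and X-linked reproductive genes, and olfactory receptors, which changed direction to 0.527. The 3 gained for promoters (zinc finger genes, olfactory and vomeronasal receptors) were excesses. With low-GC peaks, chosen after seeing the data, 2 lists passed for bodies, and germline genes fell to 0.695 times the shifts for bodies. Imprinted and germline genes fell to 0 at starts, where shifts gave 0.482 and 0.264. With 10% of the body covered, all protein-coding genes rose to 1.33 times the shifts, from 0.949. Of all placed peaks, chromosome 7 held 17.3% with the strongest 50%, 12.7% for both replicates together, 16.3% of peaks found in both own lists (chosen after seeing the data) and 12.8% to 13.2% for single replicates. The densest windows held 50.7% of covered bases with a −log10 p of at least 5, 56.6% with the strongest 50%, 37.8% for both replicates together, 51.7% for peaks found in both own lists, 52.0% in windows of 500 kb and 37.5% to 39.1% for single replicates. Repeat-masked bases were 32.3% to 34.1% for single replicates and passed as a deficit in replicate 1 alone. Among 404 values of single lists and gene classes, 375 stayed, 12 lost and 12 gained a call and 5 changed direction. The unknown depth limits what an absent peak can show.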

Other observations

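The gene families in this paragraph were scanned after seeing the data, in 273 families of at least 10 genes by symbol and 19 gene types of at least 100 genes (circular-shift permutation test with 5000 shifts, adjusted together). A first run with 1000 shifts, whose smallest adjusted p was 0.0530, let 0 of them pass, and the number was raised after that was seen. The scan found 4 families above the shifts. The variable segments of the immunoglobulin heavy chain, which are joined into antibody genes in B cells, had a replicated peak in 35 of 113 genes against 1.40 ± 3.15 in shifts (25.1 times, adjusted permutation p = 0.0130). Of these families the remaining 3 belong to the fixed lists, namely Zfp (174 of 394), Vmn (108 of 331) and Pcdhb (22 of 22). The protocadherin families Pcdha (12 of 12 against 7.71 ± 5.45) and Pcdhga (12 of 12 against 5.93 ± 5.43) did not pass (adjusted permutation p = 1 for both). The variable segments of the immunoglobulin kappa chain had 0 of 100 against 1.03 ± 1.69 in shifts and the T cell receptor variable genes 0 of 144 against 1.18 ± 1.56 (adjusted permutation p = 1 for both), and the differences between these loci were not tested. Secretoglobins (11 of 34, 5.45 times), Nlrp genes of oocytes and innate immunity (11 of 17, 2.07 times) and Cyp genes (32 of 100, 1.77 times) passed before adjustment alone, each with an adjusted p of 0.383. So did Klra (7 of 11, 4.93 times), Skint (10 of 11, 2.39 times) and Chst (7 of 14, 1.94 times), with adjusted p from 0.495 to 0.512, which makes 10 families above the shifts at an unadjusted p under 0.05. No family lay below the shifts after adjustment, and 7 did so at an unadjusted p under 0.05.

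Of 5 types of pseudogene scanned, 4 carried the mark more often than shifts gave. The limit to peaks of unique words was not applied in this scan of families and gene types. Reads shared between near-identical copies thus stay open as an explanation for its results. A replicated peak lay in 342 of 9940 processed pseudogenes against 144.5 ± 14.6 (2.37 times), in 213 of 2642 unprocessed ones against 90.8 ± 18.7 (2.35 times) and in 34 of 158 pseudogenes of immunoglobulin variable segments against 1.65 ± 2.54, each with an adjusted p of 0.0130. Transcribed unprocessed pseudogenes (53 of 253, 1.87 times) and small RNA genes without a class of their own (19 of 562, 3.64 times) had the same adjusted p. Transcribed processed pseudogenes did not differ from the shifts (22 of 296, 1.04 times, adjusted permutation p = 1). Predicted loci that await experimental checks lay below the shifts (52 of 3219, 0.572 times, adjusted permutation p = 0.0130). Along 27 imprinted genes over 4 kb, mean coverage was highest in the first of 20 bins of the gene body (31.7%) and was 0.476% in the last.

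For the X chromosome, the tests of calling threshold and of Y peaks were chosen after the result was seen, namely that replicate 1 called more X peaks than replicate 2. Over all peaks, the X ratio of replicate 1 to replicate 2 was 2.21 times the autosomal ratio. With a −log10 p of at least 5 it was 1.79 times, above every single autosome (0.883 to 1.12 times). This argues against peaks near the calling threshold as the whole cause. At that limit replicate 1 had 465 X peaks and replicate 2 had 386, against 17791 and 26435 autosomal peaks. Most of the gap in X peak number thus lay among weaker peaks, which stay open as part of the cause. Among peaks at or below the median GC content of replicate 1 the X ratio was 2.26 times the autosomal ratio, which argues against GC content. A different mix of sexes in the pools, or a different control behind the calls, stays open: replicate 1 had 11 Y peaks and replicate 2 had 21, too few to tell from the autosomal share (two-sided exact binomial test, p = 0.115), and no further biological explanation was tested. Of replicate 1's X peaks, 14.4% overlapped replicate 2, against 42.1% of its autosomal peaks, and of replicate 2's X peaks 29.6% overlapped replicate 1, against 39.1%.

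For the gene lists, splitting the test of GC content by list and adding protocadherin starts was chosen after the result was seen, and no biological explanation was tested: the 5 lists that passed for gene bodies may reflect reads shared between near-identical copies or the GC content of peaks. With the 20634 peaks whose 32-base words were at least 90% unique, 5 of the 5 lists stayed above the shifts, with ratios over 2, which argues against shared reads as the whole cause. With the 5709 peaks at or below the GC content of shifted positions, 2 of the 5 stayed, short of the bounds set beforehand (0 or all 5), so the whole test left the question open. Split by list, these were zinc finger and vomeronasal receptor genes, the lower ratio being 4.32. Protocadherin starts also stayed above the shifts (18 of 57, 48.6 times, adjusted permutation p = 0.0340). In these cases the excess was thus not confined to GC-rich peaks. The shifted positions were not matched to the low-GC peaks in GC content, so the test cannot exclude GC content as a cause. The bodies of protocadherins (6.32 times, adjusted permutation p = 0.0951), imprinted genes (2.42 times, adjusted p = 0.348) and germline genes (0.695 times, the lowest ratio) no longer passed. GC content stays open for these too, since that limit removed all but 18.5% of peaks.

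The test of the limited overlap between replicates was chosen after the result was seen. Fewer than 50% of the peaks of each replicate overlapped the other. In 4 bins of replicate 1 peaks by −log10 p, unequal in size because of ties, the overlap was 24.7%, 30.2%, 39.8% and 65.8% from weakest to strongest. The weakest bin had 0.375 times the overlap of the strongest and held 7724 of the 37557 replicate 1 peaks not shared, and the strongest held 5561. That overlap rises with strength was already known from the limit on −log10 p (64.3% against 40.9%), so peaks near the calling threshold stay open as an explanation, as do differences in depth, since read totals are unknown, and no biological explanation was tested.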
